A study of Mus musculus with 4 samples.

How the data were processed

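Total RNA of mouse ES cells was hybridised to 4 Affymetrix mouse genome arrays, each holding 45101 probe sets, of which 64 are the manufacturer's controls. Per the labels' protocols, RNA was extracted with Trizol, purified on columns and labelled with biotin by a kit that amplifies the RNA in a single cycle. The deposited value of each probe set is a signal intensity on a linear scale, computed by the authors with MAS5 per the submitters' processing notes, which give no version or settings. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 signal and usually rescales each array to a target. The deposited signals bear on this directly. The mean after leaving out the top and bottom 2% was 500.0 on each array of the Ring1B pair and 160 and 147 on the array labelled double KO control and the array labelled double KO. The 2 pairs were thus not brought to a common mean, and signals of different pairs are not comparable as deposited. No background level or detection call was used, and 2 values were listed as 0.

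The arrays were grouped by their labels into 4 groups of 1 array: Ring1B KO, its control, double KO and its control. The comparisons were the array labelled Ring1B KO against its own control, the array labelled double KO against its own control, the control arrays against each other, and the first comparison against the second. Choices of scaling, floor, thresholds, gene lists, the rule for naming genes and the alternatives were made before the data were examined. With 1 array per group no statistical test across arrays was possible and none was run.

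Each array was multiplied by a factor that brought its 2%-trimmed mean to a common 277, the geometric mean over the arrays. The factors were 0.554 and 0.554 for the Ring1B pair and 1.73 and 1.89 for the double KO pair. Signals were then floored at 36.6, the 40th percentile of all scaled signals of probe sets with 1 gene name, and log2-transformed. Scaling to a common mean assumes that the summed signal per array is alike, and a floor makes the differences of dim genes smaller than they are. A gene above the floor on 1 of 2 arrays has a lower bound in place of a fold, and a gene at the floor on both has none. List medians and counts include such genes at their bound. Saturation of bright probe sets was not assessed.

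Probe sets were named from the platform annotation. Of all probe sets, 34958 had 1 gene symbol, 932 had several and were not named, and 9211 had none here. Entrez identifiers of 34754 of them matched the RefSeq gene table, which changed 0 symbols. For the 9010 genes with several probe sets, the one with the highest mean log2 signal over the arrays was used, giving 18193 genes. Probe sets of a gene can disagree, as the Rnf2 probe sets show.

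Differences of at least 2-fold (1 on the log2 scale) were counted. Lists of genes for Hox clusters, endoderm, trophoblast, mesoderm and primitive streak, neural tissue, pluripotency, PRC1, PRC2, cell cycle inhibition and p53 response, proliferation, germline, imprinting, fibroblasts (a possible feeder layer), blood and endothelium, stress and immediate early response, housekeeping and the sex chromosomes were described by counts and by the median log2 difference. Ascl2 and Cdkn1c each stand in 2 of the 17 lists. A median was placed as a percentile among the medians of 10000 random lists of the same size, matched on mean log2 signal in 20 bins, as a description of these arrays. Lists with fewer than 5 members above the floor, which the sex-linked list was, got no percentile. List members with no name on the array here, among them Tbxt, Gapdh, H19 and Trp53, were not analysed here.

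Named genes followed a fixed rule per comparison. It took the probe sets of Ring1 and Rnf2, the 8 largest differences in each direction with both arrays above the floor, and the 4 largest bounds in each direction. Among these, predicted genes with clone-type symbols were left out, and the difference from the own control had to exceed the difference between the control arrays. The rule further asked for the same direction against the other control array, at any size. That direction follows by arithmetic from the size condition, so the rule held no separate check of it. The rule also took up to 2 members per direction of each list, and Pou5f1, Nanog, Sox2, Klf4, Esrrb and Cdkn2a in every case. For lists, members can be named whether or not they reached 2-fold.

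The steps were tested on simulated data for the double KO comparison over 18193 genes, with array noise of 0.2 on the log2 scale. Of 67 genes changed 2.5-fold, 91.0% were called at least 2-fold apart, and of 67 changed 4-fold and 66 changed 8-fold, 100% were called, with 3 calls among 11642 unchanged genes. The changed genes were drawn only from bright genes, with a mean log2 signal above that of 4 times the floor. The noise was set, alike for bright and dim probe sets, and not estimated from these arrays. These rates therefore say nothing about the recovery of dim genes. Nor do they say how many of the calls on the real arrays are false. Alternatives were the deposited scaling, quantile normalization, centring on the median, floors at the 20th and 60th percentile, adding the floor value in place of flooring, the mean over the probe sets of a gene, leaving out probe sets that can match several transcripts, the other pair's control array, the mean of both control arrays, and thresholds of 1.5- and 3-fold. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.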

Results

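Transcript levels were measured in mouse embryonic stem (ES) cells, self-renewing cells that can form the tissues of the embryo, on 4 Affymetrix mouse genome arrays. Each of 4 groups was represented by 1 array. These were ES cells labelled as a constitutive Ring1B knockout (KO), their control, ES cells labelled as a conditional Ring1A/B double KO at day 4, and their control. Ring1A (gene symbol Ring1) and Ring1B (gene symbol Rnf2) are RING-finger proteins of Polycomb repressive complex 1 (PRC1), a chromatin regulator. Of 18193 named genes, 11748 had a signal above the floor of 36.6 on the Ring1B control array and 11818 on the array labelled Ring1B KO. The array labelled double KO control had 11871 and the array labelled double KO had 11187. With 1 array per group there was no replicate check on any difference reported here, no p-value was computed, and the number of arrays limits the precision. A log2 difference is the log2 signal of the array labelled KO or double KO minus that of its own labelled control. Where the dim side was at the floor the fold is a lower bound and is given as "at least".

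The arrays fell into 2 pairs whose deposited signals had different means, and each comparison of a KO with its own control lies within a pair. Across probe sets, log2 signals correlated at r = 0.982 within the Ring1B pair and at r = 0.973 within the double KO pair, against 0.941 to 0.953 across pairs. Several control probe sets that do not represent single mouse genes also separated the pairs after scaling. One for a mouse B1 repeat read 9809 and 9168 on the Ring1B pair and 288 and 492 on the double KO pair. The 3′ to 5′ ratio of the Actb control probe sets, a measure of RNA integrity, lay between 1.16 and 1.26 on the 4 arrays, and that of Gapdh between 0.802 and 0.852. With the values as deposited, without scaling to a common mean, the median difference over genes above the floor on both arrays moved by −0.12 in the double KO comparison and by −1.61 between the control arrays.

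The targeted genes were examined first, since they check the labels. Rnf2 was under 2-fold apart in both comparisons at its brightest probe set (1424873_at). Its signal was 2579.7 on the Ring1B control array and 2775 on the array labelled Ring1B KO, and 2182 on the array labelled double KO control and 1986 on the array labelled double KO. At the next brightest Rnf2 probe set (1451519_at) the signals were 1954, 2182, 1034 and 912 in the same order. The dim probe sets 1448042_s_at (156, 134, 127 and 96.2) and 1448043_x_at (42.1, 80.2, 44.9 and 61.9) were under 2-fold apart in both comparisons, and 1448041_at was at the floor on all arrays. Whether these probe sets lie inside the deleted part of Rnf2 is not known here, and a probe set outside it checks nothing. Ring1, measured by 1 probe set (1422647_at), read 146 and 164 on the Ring1B pair and 44.7 and 55.6 on the double KO pair. It was thus 3.27-fold lower on the array labelled double KO control than on the Ring1B control array, although both are labelled wild-type, and 1.24-fold higher on the array labelled double KO than on its control. No array could therefore be assigned a genotype from its target, and the arrays are named by their labels throughout.

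In the array labelled Ring1B KO, genes of the Hox clusters, of the endoderm and of the germline had higher signals than in its control, and most pluripotency genes had slightly lower ones. In all, 437 genes were at least 2-fold higher and 322 at least 2-fold lower among 12343 genes above the floor on at least 1 of the 2 arrays, or 6.15%. The control was at the floor for 101 of the higher genes, and the array labelled KO for 45 of the lower ones. This comparison asks which transcripts differ in ES cells labelled as lacking Ring1B alone. Once a difference from the own control exceeds that between the control arrays, its direction against the other control array follows by arithmetic. Only genes meeting this size condition were ranked, and their shared direction against both control arrays is no separate check. Among these, the largest measured differences upward were in Fbp2, a muscle-type fructose bisphosphatase, which was 10.3-fold higher (95.7 to 984), and in the transcription factor gene Tfec, 8.68-fold higher (48.0 to 417). The germline genes Slc25a31, Stk31, Mael and Tex11 followed at 7.35-, 7.28-, 6.76- and 6.25-fold higher, with the Wnt antagonist gene Dkk1 at 6.55-fold and the FGF co-receptor gene Klb at 6.24-fold. Hoxd13 was at least 10.9-fold higher, Zic1 at least 6.03-fold, Hoxa10 at least 6.02-fold and Lce1h at least 5.66-fold. Against the control array of the other pair, Fbp2 differed by 1.28, Slc25a31, Stk31, Mael and Tex11 by 0.40, 0.29, 0.12 and 0.0510, and Hoxd13, Zic1, Hoxa10 and Lce1h by 0.46, 0.37, 1.08 and 0.86, so most of these sizes rest on the own control. Tfec, Dkk1 and Klb differed from it by 3.51, 3.68 and 4.50.

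Under the same condition, the largest measured differences downward in the array labelled Ring1B KO were in Calml4, 10.9-fold lower (3088 to 282), and in Dppa3, a gene of early embryos and germ cells, 5.29-fold lower (1894 to 358). Rian and Meg3, noncoding RNAs of one imprinted domain, were 4.78-fold and 3.89-fold lower. Ntn1, which encodes the guidance factor netrin 1, was 4.47-fold lower, and Pcsk1n, Trappc12 and Enpp3 were 3.96-, 3.96- and 3.88-fold lower. Slc15a2, a peptide transporter gene, was at least 10.8-fold lower, Ica1 at least 8.02-fold, Frem2 at least 5.74-fold and Ndufa4l2 at least 4.72-fold. Against the other control array Calml4, Rian, Ntn1, Enpp3, Frem2 and Ndufa4l2 were under 2-fold apart (−0.52, −0.31, −0.0393, −0.68, −0.77 and −0.91), and Dppa3, Meg3, Pcsk1n, Trappc12, Slc15a2 and Ica1 stayed at least 2-fold lower.

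Developmental gene lists stood apart in the Ring1B comparison to different degrees. Of 22 Hox cluster genes above the floor, which encode transcription factors of the body axis, 13 were at least 2-fold higher and none lower. Their median log2 difference was 1.06, above all of 10000 random gene lists matched on signal (percentile 100). Hoxa9 was 6.69-fold higher (39.5 to 264), and Hoxc6, the one lower member, differed by −0.04. Of 21 endoderm genes 14 were at least 2-fold higher, with a median of 1.99 (percentile 100). Among them were the transcription factor genes Sox7 (5.58-fold higher, 99.5 to 555) and Sox17 (5.17-fold higher, 118 to 611), while Hnf4a, near the floor, differed by −0.17. Of 15 mesoderm and primitive streak genes 5 were at least 2-fold higher, including Twist1 (3.05-fold) and Msx2 (2.59-fold), and Mesp1 differed by −0.42. Their median was 0.67 (percentile 99.96), and 0.17 with the floor at the 60th percentile. The trophoblast list had 2 of 18 members at least 2-fold higher (Krt8 2.57-fold, Esx1 2.23-fold) and 2 lower (Cdh3 and Tfap2c, 2.16-fold each), with a median of 0.12 (percentile 83.8). Of 13 neural genes Zic1 and En2 (2.69-fold) were at least 2-fold higher and Neurod1 7.33-fold lower. Their median was −0.17 (percentile 14.3), which turned to 0.14 with the values as deposited. Fibroblast marker genes moved the same way as the Hox, endoderm and mesoderm lists, with a median of 0.48 (percentile 100) and none of 17 members at least 2-fold apart.

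Most of the 29 pluripotency genes had modestly lower signals in the array labelled Ring1B KO, 21 lower and 8 higher, with a median of −0.32 (percentile 0). Pou5f1, which encodes Oct4, differed by −0.30 (5988 to 4879.6), Nanog by −0.13, Sox2 by −0.65 and Esrrb by −0.57, while Klf4 was higher by 0.48. At least 2-fold lower were Dppa3, Eras (2.74-fold) and Klf2, the last named after its values were seen, and at least 2-fold higher were Lefty2 (4.63-fold) and Tbx3 (2.43-fold). The germline genes, normally silent outside germ cells, had a median of 1.65 (percentile 100), with 10 of 15 members at least 2-fold higher and none lower. Stag3, a meiotic cohesin gene, differed by −0.64 and Smc1b by −0.17. Against the control array of the other pair, the medians of the array labelled Ring1B KO were −0.02 for the Hox list, −0.37 for the germline list, −0.25 for the mesoderm list, −0.97 for the trophoblast list and 0.18 for the pluripotency list, but 1.18 for the endoderm list. The directions of the first 5 lists therefore hold within the pair alone, as do those of Hoxa9, Hnf4a, Twist1, Msx2, Mesp1, Krt8, Esx1, Tfap2c, Neurod1, Eras, Lefty2 and Tbx3. Pou5f1, Nanog and Sox2 also turned against that control, to 0.18, 0.76 and 0.79.

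Among other lists in the Ring1B comparison, the 19 PRC1 genes had a median of 0.16 (percentile 95.1). Bmi1 was 3.91-fold higher, Cbx8 at least 2.02-fold higher and Phc1 2.01-fold lower, and Cbx7 differed by −0.70. None of the 11 genes of the partner complex PRC2 was 2-fold apart. Ezh1 differed by −0.59 and Phf19 by −0.50, and Phf1 by 0.43. The PRC2 median was −0.04 (percentile 53) and turned to 0.00105 under quantile normalization. Of 18 cell cycle inhibitor and p53 response genes, Cdkn1c was 3.06-fold higher, Cdkn2a differed by 0.99 at a low signal (37.8 to 75.3) and Bbc3 by −0.87, with a median of 0.07 (percentile 79.4). The 19 proliferation genes had a median of −0.04 (percentile 49.8), between −0.44 for Ccnb2 and 0.33 for Aurka. Imprinted genes went both ways: of 18 members, 4 were at least 2-fold higher, among them Cdkn1c and Igf2 (2.89-fold), and Meg3 was lower, with a median of 0.11 (percentile 91.1). Blood and endothelial genes had a median of −0.37 (percentile 5.36), with Pecam1 2.49-fold and Tek 2.45-fold lower. The stress and immediate early list had a median of 0.06 (percentile 83.6), with Atf3 2.96-fold and Hspa1b 2.32-fold higher. The housekeeping median was −0.14 (percentile 10.2), from −0.33 for Sdha to 0.27 for Gusb, and 0.03 under quantile normalization. Of the 3 sex-linked genes above the floor, the Y-linked Eif2s3y was 3.81-fold higher (120.4 to 459) and Uty at least 2.11-fold, and Xist differed by −0.42. Against the control array of the other pair, the PRC1, imprinted and stress medians turned to −0.17, −0.50 and −0.68, and the directions of Phc1, Phf19, Cdkn1c, Igf2, Pecam1, Atf3, Uty and Xist turned too.

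In the array labelled double KO the directions were the opposite ones. Relative to the array labelled its control, Hox, endoderm, mesoderm and germline genes had lower signals, and many pluripotency genes had higher ones. Trophoblast genes had lower signals too, but that list took no clear direction in the Ring1B comparison (median 0.12). In all, 1234 genes were at least 2-fold lower and 373 at least 2-fold higher among 12353 genes above the floor on at least 1 of the 2 arrays, or 13.0%. The array labelled double KO was at the floor for 313 of the lower genes, and the array labelled control for 64 of the higher ones. Under quantile normalization the split was less uneven, with 997 genes lower and 478 higher. This comparison asks which transcripts differ in ES cells labelled as lacking both Ring1A and Ring1B. Ranked under the same condition as above, the largest measured differences downward were in Igf2, an imprinted growth factor gene, 21.1-fold lower (5049.9 to 239), in the chemokine gene Cxcl14, 18.7-fold lower (1192 to 63.7), and in the germline gene Taf7l, 16.5-fold lower (716 to 43.4). Bmp1, Dlk1, Tdrkh, Morc4 and Igdcc3 were 12.5-, 11.8-, 11.5-, 11.2- and 10.1-fold lower. Cidea was at least 12.4-fold lower, Hoxa9 at least 11.6-fold, the endoderm transcription factor gene Gata6 at least 11.3-fold and Fbp2 at least 11.1-fold. Against the other control array Igf2, Cxcl14, Taf7l, Bmp1, Dlk1, Cidea and Hoxa9 were under 2-fold apart (−0.76, −0.53, −0.36, −0.26, −0.64, −0.0427 and −0.11), so these sizes rest on the array labelled double KO control. Tdrkh, Morc4, Igdcc3, Gata6 and Fbp2 differed from it by −1.10, −1.03, −1.18, −2.63 and −1.39.

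Under that condition, genes with higher signals in the array labelled double KO were led by Trh, the thyrotropin-releasing hormone gene, 19-fold higher (74.8 to 1424), Ntn1, 13.4-fold higher (137 to 1837), and Calml4, 9.13-fold higher (405 to 3701). Lefty1, which encodes an antagonist of Nodal signalling, was 7.01-fold higher, Patl2 6.97-fold, Pdzd4 6.92-fold, the kinase gene Pim2 6.84-fold and Xkr5 6.59-fold. Serpinb6c was at least 10.2-fold higher, Rab25 at least 9.34-fold, Trpm1 at least 8.66-fold and Pcyt1b at least 8.27-fold. Against the other control array Trh, Calml4, Lefty1, Serpinb6c and Pcyt1b were under 2-fold apart (0.48, 0.26, 0.70, 0.46 and 0.19), and Ntn1, Patl2, Pdzd4, Pim2, Xkr5, Rab25 and Trpm1 stayed at least 2-fold higher.

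Of 23 Hox cluster genes above the floor in the double KO comparison, 14 were at least 2-fold lower and none higher, with a median of −1.20 (percentile 0). The array labelled double KO was at the floor for all of these 14, so each of their sizes is a bound. The median depended on the floor, at −2.03 with the 20th percentile. Hoxd9 was at least 11.1-fold lower (406 to the floor), while Hoxa5 differed by 0.40, a direction that turned to −1.29 without probe sets that can match several transcripts and to −0.44 with the mean over its probe sets. Of 17 endoderm genes 10 were at least 2-fold lower, with a median of −1.11 (percentile 0). Col4a1, a basement membrane collagen gene, was 7.58-fold lower (1815 to 239), and the laminin gene Lama1 was the one member at least 2-fold higher, at 2.53-fold. Of 18 mesoderm and primitive streak genes 11 were at least 2-fold lower, with a median of −1.13 (percentile 0), which shrank to −0.20 with the floor at the 60th percentile. Tbx20 was at least 3.79-fold lower and Msx2 3.63-fold lower, and Mesp1 was higher by at least 0.47. Of 19 trophoblast genes 10 were at least 2-fold lower, with a median of −1.01 (percentile 0.01), among them Gata3 (9.44-fold) and Esx1 (5.29-fold), while Ascl2 differed by 0.72. The neural list split, with 7 of 19 members at least 2-fold lower and 3 higher, and a median of −0.42 (percentile 8.84). This median depended on the floor, at −1.58 with the 20th percentile and −0.0104 with the 60th. Zic1 was at least 4.68-fold and Irx3 at least 3.76-fold lower, and Gbx2 was 2.63-fold and Tubb3 2.52-fold higher. Fibroblast marker genes moved with these lists, since 12 of 17 were at least 2-fold lower, with a median of −1.73 (percentile 0). Among them, Timp3 was 6.51-fold and Postn 4.21-fold lower, and Fn1 differed by 0.28.

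Of the 29 pluripotency genes 6 were at least 2-fold higher in the array labelled double KO and 1, Tbx3, was 2.08-fold lower, with a median of 0.34 (percentile 99.98). Lefty1 was 7.01-fold and Nr0b1 4.88-fold higher. Pou5f1 differed by 0.82 (4304 to 7581), Sox2 by 0.82, Esrrb by 0.58, Nanog by 0.27 and Klf4 by −0.59. The germline genes had a median of −2.08 (percentile 0), with 15 of 18 members at least 2-fold lower and Stag3 differing by 0.17. Sycp1, a synaptonemal complex gene, was 8.29-fold lower (589 to 71.1). The fibroblast median of −1.73 lies beside this list too. Against the control array of the other pair, the medians of the array labelled double KO were −0.30 for the Hox list, −0.14 for the germline list, 0.14 for the trophoblast list and −1.59 for the endoderm list. The trophoblast direction therefore depends on which control array is used, as do the directions of Gata3, Sycp1, Tbx3, Lama1, Gbx2, Tubb3 and Mesp1, of Sox2 (−0.62) and Nanog (−0.63), and the Hox, mesoderm (−0.0783) and germline sizes.

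Other lists in the double KO comparison included the 19 PRC1 genes, with a median of 0.04 (percentile 67.3) that turned to −0.09 with the values as deposited. Phc1 was 3.61-fold higher, Phc2 3.27-fold and Bmi1 3.03-fold lower, and Pcgf2 differed by 0.42. The 11 PRC2 genes had a median of 0.05 (percentile 44.3), which turned to −0.07 with the values as deposited and under quantile normalization. Phf19 was 3.48-fold higher and Aebp2 differed by −0.94. Of 18 cell cycle inhibitor and p53 response genes 7 were at least 2-fold lower, including Cdkn1c (6.69-fold) and Pmaip1 (3.49-fold), with a median of −0.48 (percentile 0.06). Cdkn2a differed by 0.02 and Cdkn2d by 0.50. None of the 19 proliferation genes was 2-fold apart, and their median was 0.24 (percentile 98.0), with Mcm3 at 0.64 and Pcna at 0.52. Of 17 imprinted genes 6 were at least 2-fold lower, including Igf2 and Dlk1, and 3 higher, including Nnat (3.16-fold) and Peg3 (2.90-fold), with a median of −0.54 (percentile 0.03). Of 7 blood and endothelial genes Pecam1 was 6.51-fold and Tek 3.71-fold higher and Itga2b at least 2.21-fold lower. That list had a median of −0.57 (percentile 20.5), against a mean of 0.14, and the median turned to 0.13 with the floor at the 20th percentile and to 1.77 with the floor at the 60th. The stress and immediate early median was −0.17 (percentile 6.98), with Hspa1b 8.32-fold and Fos 2.72-fold lower and Egr1 differing by 0.84. The housekeeping median was 0.11 (percentile 54.0), and −0.01 with the values as deposited, with Pgk1 at 0.63 and Tbp at −0.14. Among the 3 sex-linked genes above the floor, Eif2s3y differed by 0.14, Xist by −0.23 and Uty by −0.46. Against the control array of the other pair, the imprinted, blood and stress medians turned to 0.0598, 0.16 and 0.32, and the directions of Bmi1, Fos, Aebp2, Cdkn2d, Mcm3 and Uty turned too.

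**Figure D1:**
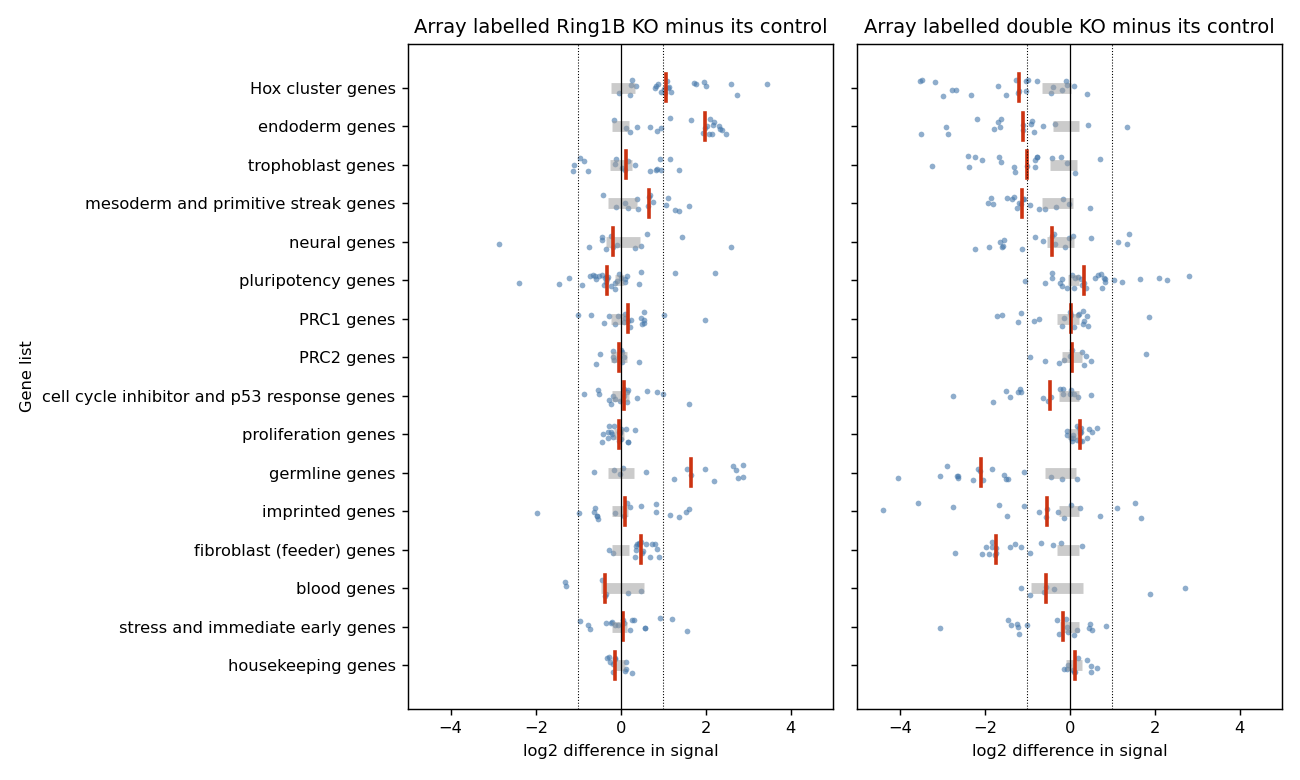
Log2 differences in signal (horizontal axis) of the members of 16 gene lists (vertical axis), for the array labelled Ring1B KO minus its control on the left and the array labelled double KO minus its control on the right, 1 array per group. Each point is a gene above the floor on at least 1 of the 2 arrays, red lines are list medians, grey bars span the central 95% of the medians of 10000 matched random lists and dotted lines mark 2-fold; the Hox median lies at 1.06 on the left and −1.20 on the right, and the germline median at 1.65 and −2.08.

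More genes were 2-fold apart between the control arrays than between either KO array and its own control. Relative to the Ring1B control array, the array labelled double KO control had 1542 genes at least 2-fold higher and 1031 at least 2-fold lower among 12645, or 20.3%. The split was 1176 higher and 1313 lower after centring on the median, and 96 and 8887 with the values as deposited, which carry the difference in mean signal between the pairs. Germline genes had a median of 1.93, trophoblast genes of 1.24, Hox genes of 1.12 and mesoderm genes of 1.07 (percentile 100 each), so the array labelled double KO control had the higher signals of all 4 lists. The endoderm median was −0.14 (percentile 8.64) and the pluripotency median −0.24 (percentile 0.58). Igf2 read 404 on the Ring1B control array and 5049.9 on the array labelled double KO control. These arrays belong to different pairs, so their differences are not assigned to a cause and cannot serve as a replicate spread.

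The 2 comparisons went in opposite directions over the transcriptome. Across 11615 genes measured in both, their log2 differences correlated at Pearson's r = −0.458 and Spearman's rho = −0.369 (covariance −0.165), where genes are not independent replicates. The 2 comparisons share no array. Of these genes, 224 were at least 2-fold higher in the Ring1B comparison and at least 2-fold lower in the double KO comparison, where independent lists of these sizes would share 40.9. Another 90 were lower in the first and higher in the second, against 9.52. The same direction was taken by 9 genes that were higher in both and 4 that were lower in both, against 12.5 and 31.2. Fbp2 (10.3-fold higher, then at least 11.1-fold lower), Mael and Taf7l were among the 224, and Calml4, Ntn1 and Enpp3 among the 90. Correlated array by array, log2 signals of the array labelled double KO were closer to the Ring1B control array (r = 0.958 across genes) than to the array labelled Ring1B KO (r = 0.941). Those of the array labelled double KO control were closer to the array labelled Ring1B KO (r = 0.952) than to the Ring1B control array (r = 0.948).

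**Figure D2:**
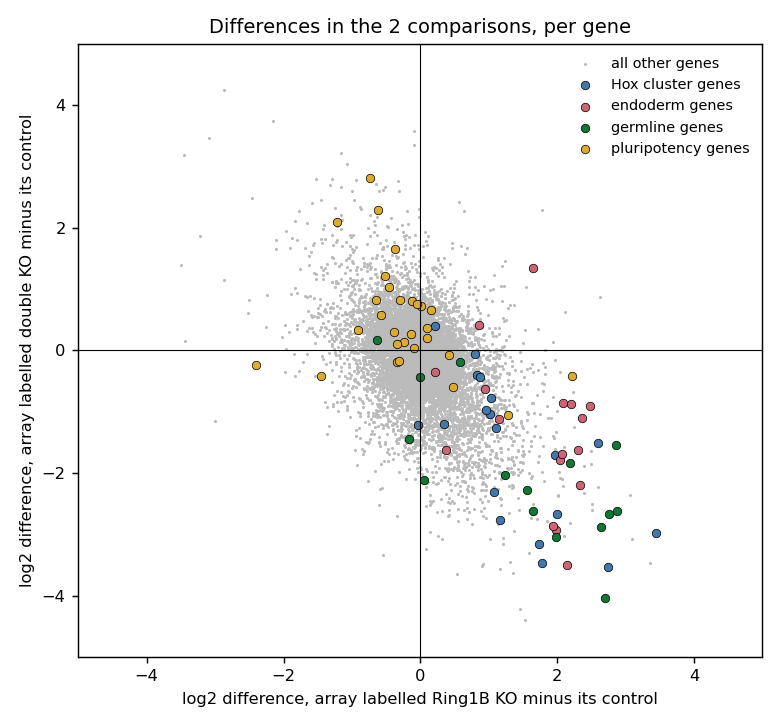
Log2 difference of each gene in the array labelled Ring1B KO minus its control (horizontal axis) against that in the array labelled double KO minus its control (vertical axis), for 11615 genes measured in both, 1 array per group. Grey points are all genes outside the coloured lists, and Hox, endoderm, germline and pluripotency genes are coloured; the correlation across genes is −0.458, and most Hox, endoderm and germline genes lie to the lower right.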

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

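The test of exchanged labels and the test of shared probe sets were fixed before their results were seen, and the tests of scaling, of a real opposite response and of feeder fibroblasts were chosen after. The results in this part stood out because the Ring1B comparison and the double KO comparison went in opposite directions. None of these differences was tested, since each group has 1 array. Values are log2 differences, with that of the array labelled Ring1B KO first and that of the array labelled double KO second, each against its own labelled control.

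The list medians were 1.06 and −1.20 for Hox cluster genes, 1.99 and −1.11 for endoderm genes, and 0.67 and −1.13 for mesoderm and primitive streak genes. Germline genes had 1.65 and −2.08, fibroblast genes 0.48 and −1.73, and pluripotency genes −0.32 and 0.34. A list was flagged only where its medians had opposite signs and both lay outside the central 95% of matched random lists. That position is therefore no separate result. Over all genes, 224 were at least 2-fold higher and then lower, and 90 at least 2-fold lower and then higher.

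In addition, 43 named genes were at least 2-fold apart in opposite directions, and they are given by list. Among Hox genes, Hoxa9 had 2.74 and −3.53, Hoxa10 2.59 and −1.51, Hoxd9 1.77 and −3.47, and Hoxd13 3.44 and −2.98. Endoderm genes were Gata6 with 2.15 and −3.50, Sox17 with 2.37 and −1.10, and Col4a1 with 1.99 and −2.92. Mesoderm, neural and trophoblast genes were Twist1 with 1.61 and −1.48, Msx2 with 1.37 and −1.86, Tbx20 with 1.27 and −1.92, Zic1 with 2.59 and −2.23, En2 with 1.43 and −1.65, Esx1 with 1.16 and −2.40, and Krt8 with 1.36 and −2.23. The neural gene Neurod1 had −2.87 and 1.14, and the pluripotency gene Tbx3 1.28 and −1.05. Germline genes were Mael with 2.76 and −2.66, Stk31 with 2.86 and −1.54, Slc25a31 with 2.88 and −2.62, Tex11 with 2.64 and −2.89, Taf7l with 2.70 and −4.04, and Sycp1 with 1.98 and −3.05.

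Among imprinted genes, Igf2 had 1.53 and −4.40, Dlk1 1.17 and −3.57, and Cdkn1c 1.61 and −2.74. The PRC1 genes Bmi1 and Phc1 had 1.97 and −1.60, and −1.01 and 1.85. The stress genes Atf3 and Hspa1b had 1.56 and −1.002, and 1.21 and −3.06, and the endothelial genes Pecam1 and Tek −1.31 and 2.70, and −1.29 and 1.89. Outside the lists, Fbp2 had 3.36 and −3.47, Cxcl14 1.45 and −4.23, and Cidea 1.35 and −3.63, while Lce1h was at least 5.66-fold higher in the first and had −1.64 in the second. Genes lower in the first and higher in the second were Calml4 with −3.45 and 3.19, Ntn1 with −2.16 and 3.75, Trh with −2.87 and 4.25, Enpp3 with −1.96 and 1.95, Patl2 with −1.29 and 2.80, Pdzd4 with −1.53 and 2.79, Rab25 with −1.16 and 3.22, and Pcyt1b with −1.07 and 3.05. Where 1 side of a comparison was at the floor the value is a bound.

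For the opposite directions as a whole, the tables argue against the scaling of the arrays as the whole source, because 1 factor per array cannot alter a correlation of log2 differences except through the floor, and quantile normalization, which reshapes each array, left it at −0.464. A candidate explanation is that the labels of the array labelled double KO and of its control are exchanged, and the correlation over 2150 probe sets with no gene name, which had not been looked at before, was also negative at −0.274. Those probe sets lie on the same arrays as the named genes, so the value is no independent check. It does not set an exchange apart from a real opposite response, which would give the same correlation of −0.458 over named genes. The marker that was to decide, a difference of at least 2-fold in Rnf2, separated neither pair, so these 2 explanations cannot be told apart here, and an exchange would turn the sign of every double KO difference from its own control. A difference in culture between the arrays of the double KO pair was not tested and stays open too, as does the different design of the knockouts, one constitutive and one conditional.

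For the germline genes, the tables argue against fibroblast feeder cells as the whole source in the array labelled Ring1B KO, where the highest of the differences of Col1a1, Col1a2 and Col3a1 was 0.525, under 2-fold, although Sparc, which also stands in the endoderm list, was higher by 1.15 (2653 to 5903) and had −1.11 in the double KO comparison. In the double KO pair feeder fibroblasts may contribute and cannot be told apart from a difference between the ES cells, since 3 of 3 collagens were at least 2-fold higher in the array labelled control, as the germline genes were, by up to 1.75. There Col1a2 read 1133 on the array labelled control and 340 on the array labelled double KO, while the abundant fibroblast genes Vim (1428 to 1246) and Fn1 (5108 to 6222), whose high level would hide a small share of feeder cells, differed by −0.20 and 0.28, and no sort that would remove feeder cells is named in the labels. Between the control arrays, collagens and germline genes did not go together. Col1a1, Col1a2 and Col3a1 read 595, 1214 and 487 on the Ring1B control array. On the array labelled double KO control they read 324, 1133 and 221, while the germline median was higher there by 1.93. These arrays belong to different pairs, so this does not settle the source. The tables argue against probe sets with a shared-transcript ending as the whole source, since only 4 of the 18 members were measured by one. Of the other 14, in the Ring1B comparison 9 of 12 above the floor were at least 2-fold higher (median 1.82). In the double KO comparison 12 of 14 were at least 2-fold lower (median −2.22). The planned test could not decide, because its medians, 1.65 and −2.16, had to stay above 2-fold in size (1.56 and −1.94 with the 4 members at 0). Cross-hybridisation of probe sets without such an ending was not tested. The Ring1B genotype itself stays among the open explanations, untested without replicates.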

How the results depend on the processing

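All alternatives in this part were chosen before the data were examined. Of the 12 alternatives, 8 keep each KO array with its own control, 2 use the control array of the other pair, and 2 alter only the fold threshold of the gene counts. Within the pairs, floors, an offset, centring and the deposited scaling can hardly turn a difference of at least 2-fold, so their agreement in direction says nothing about stability. Quantile normalization reshapes each array, but it moved each of the 177 named-gene values it gave by less than 0.721 on the log2 scale. The 102 differences of named genes of at least 2-fold and the 10 list medians of at least 1 on the log2 scale kept their direction under it. Shifts of that size could not turn the 102 differences, so this says nothing about their stability either. The mean over the probe sets of a gene altered 50 of these differences and leaving out probe sets with shared endings altered 6, and none of them turned. Of smaller values under the 8 alternatives within the pairs, 567 of 574 values of 76 named-gene results and 179 of 192 values of 24 list medians kept their direction. The correlation across genes of the 2 comparisons lay between −0.471 and −0.367 under these 8. A genewise value counts as moved where it differs by more than 0.721 on the log2 scale, a list median where it differs by more than its bootstrap SD, and a count where it differs by more than 1.5 times. The 0.721 is the spread over genes of the difference between the control arrays, and the bootstrap resamples the genes of a list. Neither measures the noise between replicate arrays. Below, the values that moved are given for the counts, the shared genes, the correlation and the medians of the 6 main lists. Centring on the median moved none of these. An alternative gives no value for a gene at the floor on both arrays, or with no probe set left.

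No paired analysis was possible because each group has 1 array and the labels give no replicate numbers, and for the same reason leaving out 1 array in turn was not possible. Signal over background limits the dim genes: between 11187 and 11871 of 18193 genes were above the floor on an array, and genes at the floor give bounds or no value.

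By construction, a lower threshold counts more genes and a higher one fewer. At 1.5-fold the genes higher and lower were 1180 and 1123 in the Ring1B comparison, 1099 and 2433 in the double KO comparison and 3298 and 2147 between the control arrays. At 3-fold they were 120 and 57, 122 and 435, and 510 and 367.

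A lower floor likewise leaves more dim genes with a large difference. With the floor at the 20th percentile, 880 genes were higher and 762 lower in the Ring1B comparison, 928 higher and 2172 lower in the double KO comparison, and 1748 lower between the control arrays. Genes shared by the comparisons were 420 higher then lower, 169 lower then higher, 45 higher in both and 48 lower in both. In the Ring1B comparison the medians were 1.55 for Hox, 0.52 for trophoblast and 0.10 for neural genes, and in the double KO comparison −2.03 for Hox, −1.70 for endoderm and −1.58 for neural genes. With the floor at the 60th percentile the counts higher and lower were 168 and 152, 218 and 530, and 982 and 638 between the control arrays. Shared genes were 72, 52, 3 and 2 in the order above. Medians were 0.58 for Hox and 0.17 for mesoderm genes in the Ring1B comparison, and −0.20 for mesoderm and −0.0104 for neural genes in the double KO comparison.

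Adding the floor value in place of flooring shrinks differences of genes above the floor on both arrays by construction. For genes with 1 side at the floor it can enlarge them. This offset gave 179 lower genes in the Ring1B comparison, 145 shared genes higher then lower, 4 higher in both and 2 lower in both. The double KO medians were −0.92 for mesoderm and −1.09 for neural genes, the latter larger in size than the −0.42 with the floor.

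With the mean over the probe sets of a gene, 992 genes were higher between the control arrays, and the medians were 1.64 for endoderm and 0.43 for mesoderm genes in the Ring1B comparison and −0.94 for mesoderm genes in the double KO comparison. Without probe sets whose ending marks several transcripts, 2 genes were lower in both. Quantile normalization gave 2 genes lower in both and a double KO mesoderm median of −0.92. The cause was not tested in these 3 cases.

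With the values as deposited, the floor of all arrays together sits at different heights on the 2 pairs by construction. The double KO comparison had 232 higher genes, the control arrays 96 higher and 8887 lower, and 10 genes were lower in both comparisons. Medians were 0.65 for trophoblast and 0.14 for neural genes in the Ring1B comparison, and −0.78 for Hox and −0.73 for mesoderm genes in the double KO comparison.

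The alternatives across the pairs mix the difference of a KO from a control with the difference between the pairs, so a reversal there does not say which of them is at work, and the cause was not tested. The difference between the pairs enters the 2 comparisons with opposite signs there, so a negative correlation across genes, −0.687 with the other control array and −0.345 with the mean of both, says nothing about the KO arrays. Of the 202 values of named genes at least 2-fold apart, 175 kept their direction, as did 17 of 20 values of list medians of at least 1. The 175 include the genes ranked under the size condition, whose direction across the pairs follows by arithmetic and could not turn. That share is therefore no measure of stability. Of smaller values, 109 of 150 and 32 of 48 did. With the control array of the other pair, the Ring1B comparison had 1001 higher and 1395 lower genes, and the double KO comparison 960 higher. Shared genes were 586 higher then lower, 474 lower then higher, 4 higher in both and 10 lower in both. The list medians of at least 1 on the log2 scale that reversed were −0.0208 for Hox and −0.37 for germline genes in the Ring1B comparison and 0.14 for trophoblast genes in the double KO comparison. Smaller Ring1B medians that turned were −0.97 for trophoblast, −0.25 for mesoderm and 0.18 for pluripotency genes, while that of endoderm genes was 1.18. Other double KO medians were −0.30 for Hox, −1.59 for endoderm, −0.0783 for mesoderm and −0.997 for neural genes.

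Named genes at least 2-fold apart that reversed in the Ring1B comparison against that control were Atf3 (−1.29), Cdkn1c (−0.46), Eras (0.74), Esx1 (−0.74), Hoxa9 (−0.68), Igf2 (−2.11), Krt8 (−1.03), Lefty2 (−0.62), Msx2 (−0.41), Neurod1 (1.71), Pecam1 (0.71), Phc1 (0.34), Tbx3 (−0.75), Tfap2c (1.15), Twist1 (−0.0945) and Uty (−0.22). In the double KO comparison they were Bmi1 (0.22), Fos (1.19), Gata3 (0.10), Gbx2 (−1.72), Lama1 (−0.75), Sycp1 (0.96), Tbx3 (0.98) and Tubb3 (−0.0129). The cause was not tested.

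With the mean of both control arrays, 822 genes were lower in the double KO comparison, and shared genes were 41 lower then higher and 32 lower in both. Igf2 (−0.29) and Tfap2c (0.0187) reversed, among genes at least 2-fold apart, in the Ring1B comparison and Gbx2 (−0.16) in the double KO comparison. Ring1B medians were 0.47 for Hox, 1.55 for endoderm, −0.45 for trophoblast, 0.000596 for mesoderm and −0.00854 for pluripotency genes. Double KO medians were −0.64 for Hox, −0.51 for trophoblast and −0.54 for mesoderm genes. The cause was not tested.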

Other observations

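The gene groups in this part and the description of the Dlk1 to Meg3 domain were chosen after the data were examined, whereas the test on Ring1 was fixed before its result was seen. Beyond the germline list, genes of the piRNA pathway, which silences transposons in germ cells, went in the same directions in part. In the Ring1B comparison 5 of 11 measured members were at least 2-fold higher and 1 lower, and in the double KO comparison 9 of 14 were at least 2-fold lower and 1 higher. Mov10l1 had log2 differences of 1.71 and −2.75 (79.2, 259, 628 and 93.5 on the Ring1B control array, the array labelled Ring1B KO, the array labelled double KO control and the array labelled double KO), Piwil2 had 1.53 and −2.30, and Gpat2 1.18 and −2.42. Tdrd12, with −1.19 and 1.38, and Pld6, with −0.67 and 0.41, went the other way. Against the control array of the other pair the piRNA medians, 0.90 and −1.89 within the pairs, were −0.79 and −0.0233. Of 9 synaptonemal complex genes, which pair chromosomes in meiosis, 4 were at least 2-fold higher in the Ring1B comparison and 6 at least 2-fold lower in the double KO comparison. Syce1 had 3.06 and −2.36 (141, 1178, 1346 and 262 on the arrays in the same order), while the bright Syce2 had −0.09 and −0.06. The synaptonemal medians were 0.94 and −1.83 within the pairs and −0.26 and 0.57 against the other control array. Mael, Ddx4, Asz1, Tdrd1, Sycp1, Sycp2, Sycp3 and Hormad1 also stand in the germline list, so these groups are not independent of it.

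The imprinted Dlk1 to Meg3 domain divided by gene in the Ring1B comparison. Its noncoding RNAs Meg3, Rian and Mirg had differences of −1.96, −2.26 and −1.72, and the protein-coding Dlk1 had 1.17. This division holds within the pair alone, since against the other control array Dlk1 had −1.76, beside −1.54, −0.31 and −0.78 for Meg3, Rian and Mirg. In the double KO comparison Dlk1 had −3.57, while Meg3, Rian and Mirg had 0.02, 0.38 and −0.18, all under 2-fold. Against the other control array this contrast was gone, with −0.64 for Dlk1 and −0.41, −1.57 and −1.12 for Meg3, Rian and Mirg. Of 11 measured matrix metalloproteinase genes, secreted or membrane-bound proteases of the extracellular matrix, 7 were at least 2-fold lower in the double KO comparison, with Mmp9 at −2.57 and Mmp13 at −1.95, which turned to 0.90 and 2.11 against the other control array. In the Ring1B comparison 0 of 9 were at least 2-fold apart. Among keratin genes, 4 of 13 were at least 2-fold lower in the double KO comparison, namely Krt19 (−2.39), Krt8 (−2.23), Krt18 (−2.08) and Krt7 (−1.67), of which Krt8, Krt18 and Krt7 also stand in the trophoblast list, and Krt42 was higher at 1.16. Against the other control array Krt19, Krt8 and Krt18 turned to 0.45, 0.17 and 1.28, Krt7 turned too, and Krt42 was at 0.00355. The simple-epithelium keratin Krt8, at 1.36, was the one keratin gene at least 2-fold apart of 14 in the Ring1B comparison, and turned to −1.03 against the other control array. The fibroblast list, of which Mmp2 is a member, had medians of 0.48 and −1.73.

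Ring1 was lower on both arrays of the double KO pair than on those of the Ring1B pair, by a mean of 3.10-fold (−1.63 on the log2 scale), although 1 of the 2 arrays is labelled as wild-type. A candidate explanation is that both arrays of this pair hold cells with an altered Ring1 gene, so that a conditional loss of Ring1B would complete the double KO. A difference between the pairs in batch or line is the alternative. Of 1960 genes with a Ring1B-pair level within 0.5 of that of Ring1, 60, or 3.06%, lay at least as far below their level there in the double KO pair, and the median of these genes was 0.11. The rule set beforehand excluded a pair difference only if none of these genes lay as far below. With 20.3% of genes at least 2-fold apart between the control arrays, that outcome was hardly possible. The share was also below the 5% set for a pair difference, so the 2 explanations cannot be told apart.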
